A study of Mus musculus with 40 samples.

How the data were processed

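Cecal contents were collected from C57BL/6 mice that were 3 weeks old when they began the Total Western Diet, a rodent chow modelled on typical Western nutrient intakes. After 6 weeks on it, they ate it for 3 more weeks either plain (0%) or with powdered broccoli making up 0.5%, 1% or 2.5% of the diet. Per the labels' protocols, total RNA was extracted from the contents, bacterial 5S, 16S and 23S ribosomal RNA was depleted with QIAseq FastSelect, and libraries were made with the KAPA RNA HyperPrep kit. The 40 libraries form 4 groups of 10, assigned from the treatment label, and replicate numbers follow the order of the samples and pair nothing.

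The deposited values are raw counts per feature, in 6 tables that each cover the genome of 1 bacterium, named as deposited: Acetatifactor, Alistipes, D. muris, F. rodentium, L.bacterium335 and X. muris. The genus abbreviations are not spelled out in the sources used here, and the aligner, counting program and genome builds are not given in the sources used here. Every column matched 1 library by name. Counts were whole numbers with no normalization, and how the counting treated reads shared by several genomes or by several copies of a gene is not given in the sources used here. Genes carrying a numeric suffix, such as susC_3, are copies of a family, and their separate counts are uncertain. Bacterial coordinates and product names were not used here, so genes appear under the symbols in the tables. A symbol was present for 38.1% of the features of Acetatifactor, 49.2% of Alistipes, 38.7% of D. muris, 47.4% of F. rodentium, 31.9% of L.bacterium335 and 18.4% of X. muris. Features without one were tested and counted, but not named.

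Each genome was fitted alone, so that a gene was measured relative to the rest of the same bacterium. Libraries with at least 10000 counts in a genome were kept, the low-count filter of edgeR (filterByExpr) was applied, and TMM factors were computed within the genome. In X. muris, 5 stable RNA features (ffs, rnpB, rrf_1, rrf_2 and ssrA) were left out of library sizes and tests. Differences between each broccoli dose and 0% were tested with edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment within genome and contrast at a threshold of 0.05, all groups sharing 1 estimate of the spread. A slope on the percent of broccoli was tested likewise. Log2 fold changes are given with standard errors obtained from the fold change and its F statistic. For genes with 0 counts in all 0% libraries only a lower bound is given, taking 3 counts over the whole group as the floor. For genes with 1 to 3 counts there, a ratio with its 95% counting interval is given. Such intervals and floors cover counting error only, and they rest on TMM scaling to the counts on the genome.

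The share of each genome among the counts of the 6 tables was compared with a two-sided permutation test of the difference in means (100000 resamples), adjusted by the Benjamini-Hochberg method over 18 comparisons. These shares say how the counts were divided among the 6 tables. They do not measure the amount of any bacterium or the rest of the community. Gene lists written before the data were examined were tested against the other genes of the genome with camera (preset correlation of 0.01, limma) where at least 5 members were tested. There were 27 lists, matched to symbols by pattern, so a few members have other known roles, which are given where they moved. Adjusted p-values with an estimated correlation are given beside the calls.

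The rule for naming genes was fixed before the data were examined. Among called genes with a symbol and an average level at or above the median of tested genes, it took the 3 largest changes each way at 2.5%, the first 2 each way at 0.5% and at 1%, and the 2 steepest trends each way. It added the called members of each list at 2.5%, up to 3 by smallest p. This gave 165 genes. The text names 92 of them, and these were chosen for length after their values had been seen: all 14 of D. muris and all 8 of X. muris, 28 of 29 of F. rodentium, 23 of 63 of L.bacterium335 and 19 of 51 of Acetatifactor. One further gene, trpE, was named after its value was seen, to complete a count.

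Total counts over the 6 tables ranged from 236483 to 5107249 per library, with a median of 825800. Per library, totals ranged from 15726 to 246887 in Acetatifactor, 51 to 44385 in Alistipes, 3108 to 172785 in D. muris, 161 to 4882829 in F. rodentium, 18763 to 814317 in L.bacterium335 and 1762 to 289859 in X. muris. No 0%, 0.5% or 1% library reached 10000 counts in Alistipes, so its genes were tested only with no minimum. All 180 pairs of libraries within groups were compared by chi-square, and 0 were identical, the smallest statistic per degree of freedom being 10.6. On data simulated from the 2.5% comparison with 200 genes changed, 4-fold changes were recovered for 65.6% of the changed genes run in Acetatifactor (747 genes run), 98.9% in D. muris (1045), 93.8% in F. rodentium (1652), 71.0% in L.bacterium335 (1304) and 94.8% in X. muris (657). For 2-fold changes these were 10.8%, 62.9%, 59.6%, 7.37% and 49.0%. False calls made up 0% to 5.19% of calls. The simulated groups had the same composition apart from these 200 genes, which changed in equal numbers up and down. These rates therefore do not cover genomes in which most genes move, as in L.bacterium335 and Acetatifactor.

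Alternatives planned before the data were examined were median-ratio (RLE) factors, DESeq2, no low-count filter, no minimum or a minimum of 50000 counts per library, stable RNA kept, a slope on the dose rank, centred log-ratios for the shares, an estimated correlation for the lists, and leaving out the libraries numbered 76 to 81. DESeq2 was run on all features with a count in the kept libraries, without the low-count filter of edgeR. Its numbers of calls are therefore not like for like with those of edgeR. The other libraries are numbered 8 to 47. Numbers 76 to 81 hold 4 mice of 0.5%, 1 of 1%, 1 of 2.5% and none of 0%, too few for a value within that set. Added after the data were seen were the genome total as a covariate, libraries with at least 50% of the features detected, the 5 most counted features of a genome left out, fits without 2.5% replicate 8 or 9, fits without a library far from its group for a named gene, and the number of features expected at an equal depth of 10000 counts. The labels give no cage, and mice of a cage share bacteria, so p-values take no account of shared cages. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.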

Results

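Bacterial RNA in the cecal contents of 40 mice was counted on 6 bacterial genomes, with 10 mice at each of 0, 0.5, 1 and 2.5% broccoli powder in a Western-type diet. The total over the 6 genomes had a median of 661900 counts per library at 0%, 970400 at 0.5%, 698400 at 1% and 889200 at 2.5%. The design asks how increasing broccoli changes which bacteria contribute RNA and which genes each bacterium transcribes. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided), and errors of log2 fold changes are standard errors. Percents of broccoli refer to the diet.

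F. rodentium supplied most of the counted bacterial RNA without broccoli and little of it at the highest dose. Its share of the 6-genome counts was 72.8% ± 17.99 (SD, n = 10) at 0%, 76.1% ± 13.2 at 0.5%, 46.1% ± 30.8 at 1% and 10.7% ± 10.6 at 2.5%. All 10 libraries at 2.5% lay below the 0% mean (permutation test, adjusted p = 0.00018). L.bacterium335 rose from 14.3% ± 11.5 at 0% to 50.4% ± 8.88 at 2.5%, with 10 of 10 libraries above the 0% mean (permutation test, adjusted p = 0.00024). At 0% a median of 76.8% of the counts on L.bacterium335 lay on the 5 most counted features. Of the 10 libraries, 2.5% replicate 9 resembled the 0% group, with 79.15% on 5 features. Only 399 of its 101772 counts on L.bacterium335 lay on genes called higher at 2.5%. Whether counts on so few features came from this bacterium was not tested. Alistipes rose from 0.0240% ± 0.0157 to 0.170% ± 0.170 at 1% (permutation test, adjusted p = 0.00027) and 1.58% ± 0.981 at 2.5% (permutation test, adjusted p = 0.00018). The smallest unadjusted p that these permutations can give is 2e-05.

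X. muris rose from 2.64% ± 1.47 of the counts at 0% to 5.99% ± 3.75 at 1% and 11.8% ± 6.76 at 2.5% (permutation test, adjusted p = 0.0178 and 0.000864). D. muris rose from 3.80% ± 2.93 to 8.14% ± 3.33 at 1% and 8.97% ± 4.75 at 2.5% (permutation test, adjusted p = 0.0142 and 0.0131). Each of these bacteria was above its 0% mean in 9 of 10 libraries at 2.5%. Acetatifactor rose from 6.44% ± 4.23 to 16.6% ± 13.96 at 2.5%, in 8 of 10 libraries (permutation test, adjusted p = 0.0308). At 0% a median of 89.9% of X. muris counts and 56.8% of Acetatifactor counts lay on the 5 most counted features of each genome. Whether these counts came from those bacteria was not tested. At 0.5% none of the 6 shares passed the test, with adjusted p from 0.182 to 0.718 by permutation, and at 1% those of F. rodentium, L.bacterium335 and Acetatifactor missed it (0.0554, 0.131 and 0.165). Shares add up to a whole, so the fall of F. rodentium raises the others. As centred log-ratios, Acetatifactor (-0.23) and D. muris (-0.11) lay below 0% at 2.5%, and L.bacterium335 (0.89, adjusted p = 0.105) and X. muris (0.60, adjusted p = 0.342) missed the permutation test. In these ratios the rise of Alistipes (4.59) lowers the other values, as the fall of F. rodentium (-5.74) raises them. Without 2.5% replicate 9, whose share of Acetatifactor was 51.8%, the Acetatifactor difference was 6.25 points (permutation test, adjusted p = 0.0554).

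**Figure D1:**
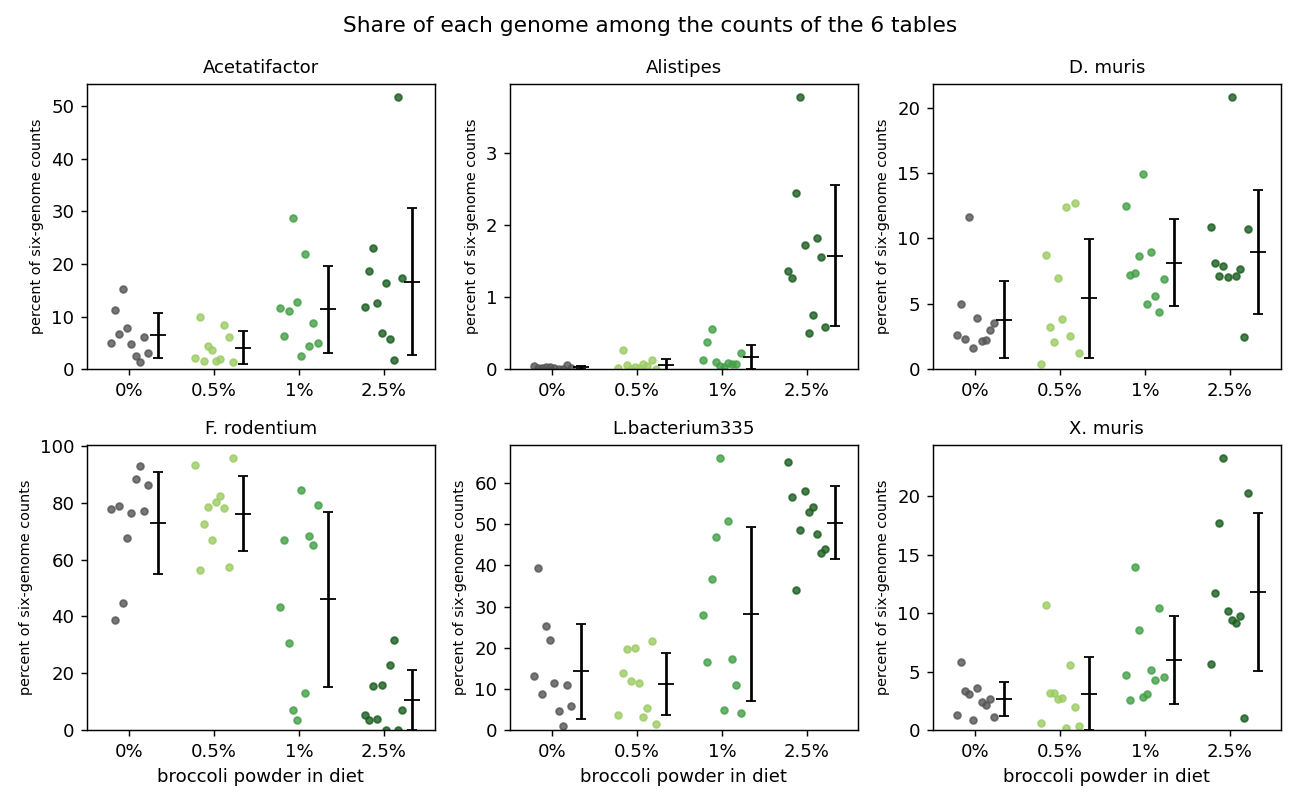
Share of each bacterial genome among the counts of the 6 genomes, in percent, for each of the 40 libraries by percent of broccoli powder in the diet. Each point is a library and the black bar beside it is the mean ± SD of 10 libraries. F. rodentium goes from a mean of 72.8% at 0% to 10.7% at 2.5%, and L.bacterium335 from 14.3% to 50.4%.

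In L.bacterium335, most of the measured transcriptome was close to absent without broccoli and present at every dose, apart from 2.5% replicate 9. Genes of glycogen synthesis were at least 538-fold (glgD) and 478-fold (glgC_1) higher at 2.5% than at 0%, where all 10 libraries held 0 counts for them. The arabinose transporter gene araQ_1 was at least 669-fold higher, and the recombinase gene xerD_1 at least 510-fold higher. These bounds use the floor of 3 counts over the 0% group, and 9 of 10 libraries at 2.5% lay above the 0% mean for each of these genes. All such bounds are scaled to the counts on this genome with TMM factors. They would be smaller if part of its 0% counts came from other bacteria. The flagellar cap gene fliD had 6 counts at 0% and rose by a log2 fold change of 9.20 ± 0.89 (edgeR adjusted p = 2.98e-15, n = 10 each), above the 0% mean in 10 of 10 libraries.

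All 26 tested flagella and chemotaxis genes of L.bacterium335 rose at 2.5%, also 26 when adjusted over the list alone, among them the chemotaxis gene cheV (at least 330-fold). All 8 genes of uronate and pectin sugar catabolism rose, 8 over the list alone, including kdgK (at least 208-fold) and kduI (at least 134-fold), which degrade pectin-derived uronates. The arabinose isomerase gene araA was at least 124-fold higher and the galactanase gene ganB at least 57.6-fold higher. The pectinesterase gene pemA rose by 6.04 ± 0.83 on the log2 scale (edgeR adjusted p = 4.3e-10), and by 9.59 without 0% replicate 4. ATP synthase genes rose in 6 of 6, with atpB at least 234-fold and atpG at least 192-fold higher, and ribosomal protein genes in 29 of 33 (28 over the list alone), with rplA at least 173-fold higher. Fermentation genes rose in 7 of 7, among them pyruvate formate-lyase pflB_1 (5.96 ± 0.70, edgeR adjusted p = 2.77e-12). Acetate kinase ackA had 1 count at 0% and a ratio of 645, with a counting interval of 116 to 25500. The butyrate pathway gene thlA was at least 80.1-fold higher, and all 16 heat shock and protease genes rose, the chaperone gene dnaK with a ratio of 964 (interval 173 to 38100). On the log2 scale ackA went from 8.80 to 10.71 without 0% replicate 6, and dnaK from 9.46 to 11.36 without 0% replicate 5. All 5 sporulation genes rose, spoVG by at least 170-fold. No list stood apart from the remaining genes by camera (flagella and chemotaxis, adjusted p = 0.106, and 0.724 with an estimated correlation), while without libraries 76 to 81 the flagella and chemotaxis list did (camera adjusted p = 0.0468).

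Of 1384 genes tested in L.bacterium335, edgeR called 1109 at 0.5% (1099 higher), 1106 at 1% (1085 higher) and 1285 at 2.5% (1077 higher, 208 lower). Of the 1077 higher genes, 903 had 0 counts in every 0% library, out of 757208 counts on this genome there, and their median lower bound was 48.1-fold. The 0% counts lay on few features, with a median of 76.8% on the 5 most counted, against 18.1% at 2.5%. Among genes that fell at 2.5%, yjdF_2 fell by 3.21 ± 0.71 on the log2 scale and mftC by 3.34 ± 0.89 (edgeR adjusted p = 2.57e-05 and 0.000371). The histidine synthesis gene hisC_3 (-1.89 ± 0.54, edgeR adjusted p = 0.000886) and the helicase gene recD2_1 (-1.22 ± 0.56, edgeR adjusted p = 0.0344) turned to 0.07 and 0.71 with RLE factors, and mftC lost its call (adjusted p = 0.0682). Without 2.5% replicate 9 the falls of hisC_3, recD2_1 and mftC were -2.78, -1.94 and -4.49. All these falls are relative to the other genes of the genome. Unscaled, the summed counts on the 208 genes called lower overlapped, with 17237 to 116833 per library at 0% and 41669 to 96902 at 2.5%. This sum does not show single genes. RLE factors moved the median log2 fold change from 7.94 to 9.20 and the split to 1147 higher and 33 lower, and DESeq2 called 2821 higher and 48 lower. DESeq2 was run without the low-count filter, so its counts are not out of the 1384 genes. The dose slope was called for 638 genes (467 rising), for 1033 without 2.5% replicate 9 and for 543 without replicate 8. It was called for 254 with a minimum of 50000 counts and for 0 with the genome total as a covariate (edgeR, 170 at an unadjusted p under 0.05), while DESeq2 without it called 2918.

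**Figure D2:**
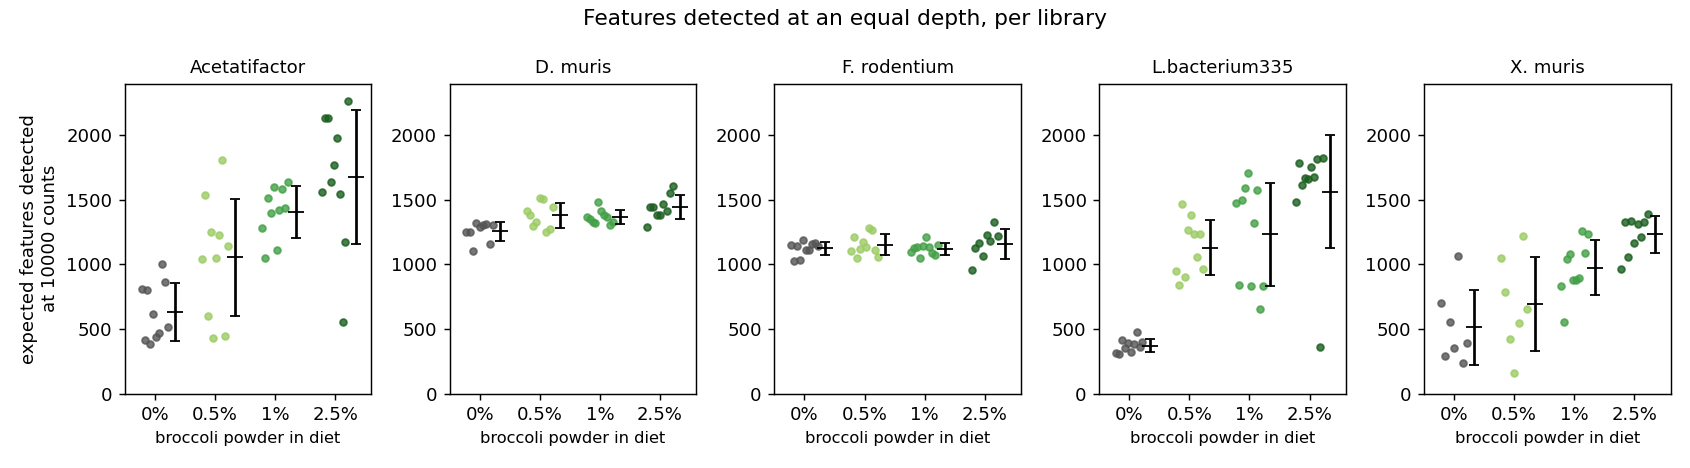
Number of features with at least 1 count expected when each library is reduced to 10000 counts in a genome, by percent of broccoli powder, for 5 genomes. Each point is a library and the black bar beside it is the mean ± SD. In L.bacterium335 the mean is 371.8 at 0% and 1564 at 2.5%, and in F. rodentium 1123 and 1159.

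In Acetatifactor at 2.5%, the dipeptide permease gene dppB_1 rose by 5.75 ± 0.90 on the log2 scale (edgeR adjusted p = 3.52e-06, n = 10 each) and the transporter gene btuD_20, named for an ABC transporter subunit, by 5.02 ± 0.88 (edgeR adjusted p = 1.58e-05). The abundant gene agpA rose from 530.6 to 12240 CPM (4.53 ± 0.87, edgeR adjusted p = 3.73e-05). CPM are counts scaled to a library's total over the tested genes of the genome, adjusted by its TMM factor. The sporulation regulator gene spo0A rose by 4.22 ± 0.86 (edgeR adjusted p = 7.74e-05). These genes were above the 0% mean in 9 of 10 libraries, the exception being 2.5% replicate 8. Without 0% replicate 3 btuD_20 was 6.85 higher.

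Of 12 ribosomal protein genes of Acetatifactor, 11 rose at 2.5% (12 over the list alone), among them rplE (3.94 ± 0.79) and rpsC (3.65 ± 0.82), with camera adjusted p = 0.0635, 0.722 with an estimated correlation and 0.0315 without libraries 76 to 81. Over the dose slope 9 of the 12 rose (11 over the list alone), with camera adjusted p = 0.0421 and adjusted p = 0.633 with an estimated correlation. All 7 fermentation genes rose, including pflB_1 (2.97 ± 0.69), as did 3 of 3 butyrate pathway genes, including thlA (3.28 ± 0.74) and hbd (3.04 ± 0.71). The fermentation list did not stand apart by camera (adjusted p = 0.142, and 0.722 with an estimated correlation). The butyrate list was too short to test, and 421 of all 773 tested genes rose. The plant sugar genes kduD (3.75 ± 0.80), rhaB for rhamnose (2.92 ± 0.77) and fucI for fucose (2.07 ± 0.70) rose, as did yesX (1.93 ± 0.68) and the branched-chain synthesis gene ilvC (2.25 ± 0.79). Without 0% replicate 1 rpsC was 6.16 higher, and without 0% replicate 8 ilvC was 6.00 higher. The ATP synthase gene atpG had 3 counts at 0% and a ratio of 36.8 with a counting interval of 12.5 to 179.

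Of 773 Acetatifactor genes, edgeR called 194 at 0.5% (167 higher), 524 at 1% (383 higher), 595 at 2.5% (421 higher, 174 lower) and 488 for the dose slope (321 rising). Among those that fell at 2.5% were cpdA_3 by -3.39 ± 0.76, the sensor kinase gene rcsC_8 by -3.22 ± 0.60, the response regulator gene graR_4 by -3.20 ± 0.70 and the flagellar sigma factor gene fliA_2 by -2.95 ± 0.77. With RLE factors, which moved the median log2 fold change at 2.5% from 1.81 to 3.84, these values were -1.07, -1.08, -1.10 and -1.40 and none was called (edgeR adjusted p from 0.0556 to 0.195). Falls here are relative to the other genes of the genome. Unscaled, the summed counts on the 174 genes called lower overlapped, with 16921 to 44885 per library at 0% and 15798 to 62181 at 2.5%. This sum does not show single genes. Of 7 flagella and chemotaxis genes 6 rose and fliA_2 fell, 6 and 1 over the list alone (camera adjusted p = 0.397, and 0.727 with an estimated correlation). RLE gave 543 genes higher and 21 lower at 2.5%, and without libraries 76 to 81 the 0.5% dose gave 87 calls, all higher.

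In D. muris, a polysaccharide uptake gene and an antibiotic resistance gene took a smaller part of the genome's counts at every dose, and a mobile element gene at 0.5 and 2.5%. The gene susC_3, of the SusC family of outer membrane polysaccharide transporters, went from 13360 ± 4737 CPM (SD, n = 9) to 1908 ± 745.4 (n = 9) at 2.5%. Its log2 fold changes were -1.78 ± 0.33, -1.90 ± 0.32 and -2.81 ± 0.34 at 0.5, 1 and 2.5% (edgeR adjusted p = 0.0005, 8.8e-05 and 5.12e-08), below the 0% mean in 9 of 9 libraries at 2.5%. The tetracycline resistance gene tet(Q) fell by 1.93 ± 0.35, 1.75 ± 0.33 and 2.02 ± 0.35 (edgeR adjusted p = 0.0005, 0.000399 and 3.8e-05). The intron reverse transcriptase gene ltrA_1 fell by 2.20 ± 0.47 at 0.5% and 2.76 ± 0.47 at 2.5% (edgeR adjusted p = 0.00257 and 3.72e-05), and glcA by 1.66 ± 0.46 and 3.42 ± 0.48 (edgeR adjusted p = 0.0219 and 1.4e-06). These falls are relative to the rest of the genome, whose median total went from 25670 at 0% to 91090 at 2.5%. Unscaled, the summed counts on all genes called lower at 2.5% did not drop. They were 3064 to 9497 per library at 0% and 5359 to 14902 at 2.5%. This sum covers 74 genes and does not show how the unscaled counts of susC_3, tet(Q), ltrA_1 or glcA alone changed.

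In D. muris 2 of 6 tested genes of branched-chain amino acid synthesis rose at 2.5%, and 5 adjusted over the list alone. The acetolactate synthase gene ilvB rose by 1.44 ± 0.35 and the isopropylmalate isomerase gene leuC by 2.13 ± 0.58 (edgeR adjusted p = 0.00262 and 0.0101). The list stood apart by camera (adjusted p = 0.0303), a call lost at adjusted p = 0.51 with an estimated correlation. Its slope likewise gave adjusted p = 0.034, and adjusted p = 0.565 with an estimated correlation. Of 5 SusC/SusD genes, 1 fell (2 over the list alone; camera adjusted p = 0.0924, and 0.219 with an estimated correlation), and of 40 ribosomal protein genes 2 rose, rpsS (1.89 ± 0.54) and rplB (0.65 ± 0.21), or 1 over the list alone. The vitamin B12 receptor gene btuB_4 (1.10 ± 0.35) and the cell division gene ftsI (0.87 ± 0.29) rose, and the thioredoxin gene trxA_1 (-1.56 ± 0.35) and the methylmalonyl-CoA mutase gene mutB (-0.56 ± 0.18) fell. At 1% the GMP synthase gene guaA (0.89 ± 0.27) and the serine synthesis gene serC (0.53 ± 0.16) rose (edgeR adjusted p = 0.0369 and 0.0319). EdgeR called 55 of 1108 genes at 0.5% (20 higher, 35 lower), 69 at 1% (28, 41), 117 at 2.5% (43, 74) and 92 for the slope (25, 67). Without libraries 76 to 81 the 0.5% count was 18 and the calls of ftsI and mutB were lost (edgeR adjusted p = 0.0508 and 0.0857), and without 2.5% replicate 8 those of btuB_4, mutB and rplB (0.0505, 0.0535 and 0.0511). With libraries holding at least 50% of the features leuC (1.80, edgeR adjusted p = 0.0720), ftsI, mutB and rplB lost their calls, as did btuB_4 and ftsI without 0% replicate 3 (edgeR adjusted p = 0.0525 and 0.0550). With the genome total as a covariate 17 genes were called at 2.5% and 0 for the slope, with 56 slopes at an unadjusted p under 0.05, while DESeq2 without it called 131.

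**Figure D3:**
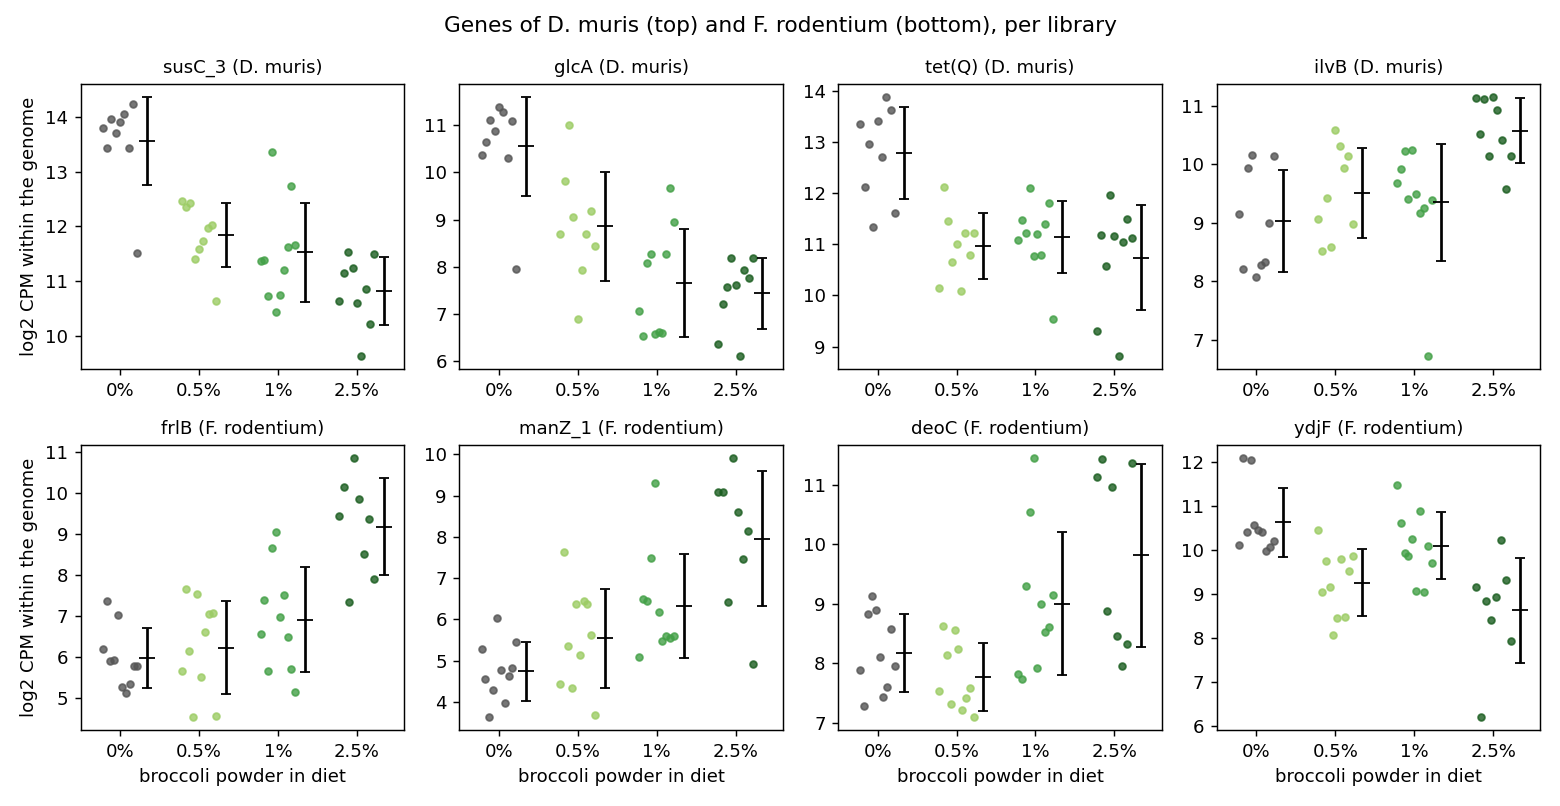
Log2 CPM of 4 genes of D. muris (susC_3, glcA, tet(Q), ilvB) and 4 of F. rodentium (frlB, manZ_1, deoC, ydjF) by percent of broccoli powder. Each point is a library with at least 10000 counts in the genome and the black bar beside it is the mean ± SD. At 2.5% against 0%, susC_3 differs by -2.81 and frlB by 3.54 on the log2 scale.

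In F. rodentium at 2.5%, the gene frlB rose by 3.54 ± 0.49 on the log2 scale (edgeR adjusted p = 1.5e-06, n = 10 and 8). Its product splits fructoselysine 6-phosphate, the phosphorylated form of a glycation product in heated food. The mannose phosphotransferase gene manZ_1 rose by 3.70 ± 0.56 (edgeR adjusted p = 9.77e-06). Both frlB and manZ_1 were above the 0% mean in 8 of 8 libraries. The deoxyribose-phosphate aldolase gene deoC rose by 2.09 ± 0.45 (edgeR adjusted p = 0.00221) and the galactitol transport gene gatC_2 by 1.65 ± 0.39 (edgeR adjusted p = 0.00544). Of 11 phosphotransferase system genes 2 rose (3 rose and 1 fell over the list alone; camera adjusted p = 0.162). The sugar-binding gene mglB rose by 4.59 ± 0.38 at 0.5% and 2.40 ± 0.41 at 2.5% (edgeR adjusted p = 2.87e-12 and 7.29e-05), and licC by 1.57 ± 0.29 and 1.62 ± 0.31 (edgeR adjusted p = 0.000402 and 0.000427).

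Of 7 tryptophan genes of F. rodentium, 4 rose at 2.5% (5 over the list alone): trpB (1.99 ± 0.59), trpD (2.09 ± 0.65), trpF (2.13 ± 0.62) and trpE (1.39 ± 0.43), all of tryptophan synthesis. At 2.5% trpB, trpD and trpF were above the 0% mean in 6, 7 and 5 of 8 libraries. Camera gave adjusted p = 0.0354, a call lost without libraries 76 to 81 (adjusted p = 0.0546) and with an estimated correlation (adjusted p = 0.486). None of 28 purine and pyrimidine genes was called by edgeR, also 0 over the list alone, while their median log2 fold change of 0.27 stood apart (camera adjusted p = 0.00756, and adjusted p = 0.486 with an estimated correlation). Of 15 glycolysis genes 3 fell (5 over the list alone), the mutase gene gpmA_4 (-1.05 ± 0.21, edgeR adjusted p = 0.000776), pfkA (-0.64 ± 0.17) and gpmI (-0.51 ± 0.14), with camera adjusted p = 0.109. The pentose phosphate gene rpiA (-1.13 ± 0.26, edgeR adjusted p = 0.00365) also fell. Of 9 oxidative stress genes 3 fell (4 fell and 1 rose over the list alone), rubrerythrin rbr1 (-0.70 ± 0.20), thiol peroxidase tpx (-0.83 ± 0.24) and thioredoxin reductase trxB (-0.60 ± 0.20). The bile salt hydrolase gene cbh_1 fell by 1.32 ± 0.25 at 0.5% and 1.15 ± 0.27 at 2.5% (edgeR adjusted p = 0.000402 and 0.00546), and the regulator gene ydjF by 1.42 ± 0.34 and 1.82 ± 0.38 (edgeR adjusted p = 0.00591 and 0.00165).

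Of 11 genes on the plant cell wall list of F. rodentium 3 rose at 2.5% (4 over the list alone): manZ_1, which takes up mannose, and the beta-glucoside genes bglC (0.81 ± 0.25) and bglK_1 (1.53 ± 0.51), with camera adjusted p = 0.0800. The arabinose pathway gene araD (1.65 ± 0.51), the methionine synthase gene metH_2 (1.11 ± 0.31) and hemE of heme synthesis (2.06 ± 0.51) rose. The chaperone gene htpG (-0.89 ± 0.25), the cysteine synthesis gene cysE_1 (-1.13 ± 0.35), cobB (-0.87 ± 0.29) and the cell wall gene murD (-0.97 ± 0.29) fell. The call of the glycogen phosphorylase gene glgP_1 at 0.5% (-1.80 ± 0.41, edgeR adjusted p = 0.00347) rested on 0% replicate 1, without which it was -0.62 ± 0.25 (edgeR adjusted p = 0.114). At 1% hemE rose by 2.03 ± 0.48 (edgeR adjusted p = 0.0282), 1 of 8 calls (4 without 0% replicate 1, and 5 without 1% replicate 5). EdgeR called 143 of 1689 genes at 0.5% (60 higher, 83 lower), 8 at 1% (8 higher), 159 at 2.5% (91, 68) and 101 for the slope (57, 44). Without 0% replicate 2 the 0.5% count was 94. Without libraries 76 to 81 the 0.5% count was 40 and the 2.5% count 102, and araD, bglC, bglK_1, cobB, cysE_1, gpmI, murD, trpB, trpF and trxB lost their calls at 2.5% (edgeR adjusted p from 0.0521 to 0.118). With a minimum of 50000 counts bglC, bglK_1, cobB, cysE_1, gpmI, htpG, metH_2, murD, rbr1, tpx, trpD and trxB lost theirs (edgeR adjusted p from 0.0515 to 0.143), including all 3 oxidative stress genes. Without 2.5% replicate 8 those of araD, bglK_1 and trpF were lost (edgeR adjusted p from 0.0555 to 0.114), and RLE factors split the 2.5% calls into 111 higher and 45 lower, with a median shift from 0.01 to 0.12.

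In X. muris at 2.5%, the uronate isomerase gene uxaC rose by 2.21 ± 0.61 on the log2 scale (edgeR adjusted p = 0.00734, n = 7 and 9) and the ribonuclease gene rnr by 2.43 ± 0.54 (edgeR adjusted p = 0.000362), with 2.39 ± 0.61 and 2.18 ± 0.55 at 1% (edgeR adjusted p = 0.00452 and 0.00425). The aldehyde dehydrogenase gene aldA rose by 1.85 ± 0.54 and the pyruvate oxidoreductase gene nifJ by 1.14 ± 0.35 (edgeR adjusted p = 0.0128 and 0.0183). The mobilization gene mobV_1 fell by 1.80 ± 0.38 (edgeR adjusted p = 0.000184). Each of these was on the called side of the 0% mean in 9 of 9 libraries. The fall of mobV_1 is relative to the rest of the genome, whose median total went from 16000 at 0% to 120000 at 2.5%. Unscaled, the summed counts on all X. muris genes called lower did not drop. This sum was 8822 to 34374 per library at 0% and 27995 to 121980 at 2.5%, and does not show mobV_1 alone.

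The glutamate dehydrogenase gene gdhA (1.19 ± 0.40), the methylmalonyl-CoA epimerase gene mce (1.65 ± 0.58) and the pyruvate phosphate dikinase gene ppdK (0.97 ± 0.34) of X. muris also rose (edgeR adjusted p = 0.0341, 0.0466 and 0.0466). None of 26 ribosomal protein genes was called by edgeR, also 0 over the list alone, with camera adjusted p = 0.855. Of 670 genes, edgeR called 44 at 1% (36 higher, 8 lower), 74 at 2.5% (64, 10) and 49 for the slope (31, 18). At 0.5% edgeR called 0, with 89 at an unadjusted p under 0.05, and DESeq2 called 0, but without 0.5% replicate 5 edgeR called 7, among them rnr (2.37 ± 0.54, edgeR adjusted p = 0.0218). Without 0% replicate 9 the 2.5% count was 49. RLE factors, which moved the median log2 fold change at 2.5% from 0.51 to 0.25, gave 32 higher and 13 lower, and DESeq2 gave 32 higher and 23 lower; gdhA, mce, nifJ and ppdK then lost their calls with RLE (edgeR adjusted p from 0.114 to 0.223). Without 2.5% replicate 8 the calls of gdhA, mce and ppdK were lost (edgeR adjusted p from 0.0767 to 0.108), without libraries 76 to 81 those of mce and ppdK (0.0548 and 0.0517), and with no minimum of counts those of uxaC and ppdK (0.0700 and 0.203).

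Alistipes held a median of 132 counts per library at 0%, 357.5 at 0.5%, 620.0 at 1% and 11220 at 2.5%. It had 7 libraries with at least 10000 counts, all at 2.5%, so no gene was tested at that minimum. With no minimum edgeR tested 7 features and called 1 at 0.5%, 1 at 1% and 2 at 2.5%, picked from this alternative after the result was seen. They were a feature without a gene symbol, higher at each dose (log2 fold change 6.09 at 2.5%, edgeR adjusted p = 3.07e-10), and the ribosomal protein gene rpmE2 (-0.90, edgeR adjusted p = 0.0378).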

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

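The test of L.bacterium335 calls after thinning, the use of 10 thinnings with their spread in place of 1, the slopes on counts outside the called genes, within a group or without a library, the fits without a single library far from its group, and the features at an equal depth were chosen after the results were seen, as was the selection of genes printed here. A library was picked out when its gap to the nearest other library of its group was large against the group's range, which chance does in about 1 of 20 groups. This happened 90 times in 403 groups of libraries for the shares, totals, feature numbers and the 92 genes named in the text. Over all 165 genes of the naming rule it happened 175 times in 618 groups, 57 of them for 2.5% replicate 9 being lowest in L.bacterium335 and 40 for 2.5% replicate 8 being lowest in Acetatifactor.

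In L.bacterium335, 2.5% replicate 9 had 359.7 features at an equal depth against 1483 in the next library, close to the 0% group's mean of 371.8 ± 51.4. It was lowest, at the floor of 2.87 log2 CPM, for ackA, araA, araQ_1, atpB, cheV, dnaK, ganB, glgC_1, glgD, kdgK, kduI, pemA, rplA, spoVG, thlA and xerD_1, and at 5.02 for atpG, 5.49 for fliD and 5.84 for pflB_1. It was highest for hisC_3 (10.50), mftC (7.51) and recD2_1 (10.36), and its share of Acetatifactor, 51.75%, was the highest of its group. In Acetatifactor, 2.5% replicate 8 was lowest, at the floor of 4.84, for agpA, atpG, btuD_20, dppB_1, fucI, hbd, ilvC, kduD, pflB_1, rhaB, rplE, rpsC, spo0A, thlA and yesX.

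Other libraries far from their group in Acetatifactor, in log2 CPM, were 0% replicate 1 for rpsC (8.03), 0% replicate 3 for btuD_20 (7.64), 0% replicate 8 for ilvC (9.49), and 0.5% replicate 6 for graR_4 (10.13), all high. At 2.5% replicate 4 was high for graR_4 (8.43) and rcsC_8 (9.56), and 1% replicate 6 was low for atpG (4.84), hbd (6.51) and rplE (5.90). In L.bacterium335, single 0% libraries were high for pemA (5.63, replicate 4), dnaK (4.20, replicate 5) and ackA (4.21, replicate 6), and replicate 8 low for hisC_3 (8.40). At 0.5% replicate 7 was low for glgD (8.53) and spoVG (2.87), and 1% replicate 6 for atpB (5.68).

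In D. muris, 0% replicate 3 was low for btuB_4 (5.10) and ftsI (5.10), and 0% replicate 10 for glcA (7.94) and susC_3 (11.52). At 0.5% replicate 6 was low for serC (10.46) and replicate 9 for rpsS (6.43). At 1% replicate 9 was low for ftsI (8.15) and ilvB (6.72), and replicate 10 for tet(Q) (9.54). At 2.5% replicate 1 was high for serC (11.93) and low for rpsS (7.26), and replicate 4 low for leuC (5.82). In F. rodentium, 0% libraries were high for glgP_1 (13.95, replicate 1), tpx (10.06, replicate 2) and licC (10.64, replicate 10). At 1% replicate 4 was low for gpmA_4 (7.94) and hemE (1.74), and replicate 5 for araD (1.74), murD (7.08) and rpiA (6.67). At 2.5% replicate 1 was low for gatC_2 (1.74) and replicate 2 for htpG (8.27) and murD (1.74). In X. muris, 0% replicate 9 was low for rnr (4.43), 0.5% replicate 5 for aldA (4.43), mce (4.43), ppdK (7.71) and rnr (4.43), 1% replicate 1 for uxaC (6.40) and 1% replicate 2 for nifJ (9.96).

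Shares far above the rest of their group were 0.2612% of Alistipes (0.5% replicate 2), 11.65% and 20.81% of D. muris (0% replicate 4 and 2.5% replicate 6) and 10.68% of X. muris (0.5% replicate 2), and the 6-genome total of 0.5% replicate 10 was 5107249. Among features kept out of the tests, ssrA took 0.1611% ± 0.0876 of X. muris counts at 2.5% against 0.0334% ± 0.0331 at 0%, and rnpB 0.02669% ± 0.0133 against 0.00413% ± 0.00868 (SD, n = 10 each).

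The rise of most tested genes of L.bacterium335 and Acetatifactor from 0% to 2.5%, and the calls in X. muris, go with a rise in each genome's total. The tables argue against depth as the whole cause in L.bacterium335, where 104 of the 148 genes still testable in 1 thinning to 10000 counts were called (70.3%, against 1384 tested in full), and in Acetatifactor and X. muris, where thinning kept 0.854 ± 0.017 and 0.901 ± 0.068 (SD of 10 thinnings) of the median change, although calls there dropped to 74 of 175 genes and to 10 of 114 (4 higher and 6 lower, against 64 and 10 in full). In L.bacterium335 that ratio, 0.504 ± 0.011, lay between its bounds, so thinning cannot tell the size of the 2.5% change from depth. At 0.5% the median total was no higher (77240 against 83650 at 0%). The median log2 fold change there was still 7.60, with 1099 of 1384 genes higher. At an equal depth 10 of 10 of those libraries showed more features than every 0% library. These values argue against depth as the cause at 0.5%, though the fold size rests on genes near the floor at 0%. A second source of counts on a few features, such as reads of other bacteria, may contribute, beside a change in the bacterium's abundance with broccoli, cage and changed transcription, which stay open, untested: slopes of higher over lower counts on the genome total within diet groups (1.20 ± 0.29, 1.37 ± 0.39 and 0.55 ± 0.21; SE, n = 40, 40 and 33) are partly built in, since called genes held a median of 96.0%, 91.0% and 92.2% of that total at 0%, but on the counts outside those genes they were 1.39 ± 0.20, 1.40 ± 0.28 and 0.61 ± 0.07. In L.bacterium335 these slopes were 0.63 ± 0.19 and 0.85 ± 0.14 without 2.5% replicate 9, and within the 0% group alone -0.68 ± 0.32 and -0.15 ± 0.63.

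In D. muris, susC_3, tet(Q), glcA and ltrA_1 were among 74 genes that fell and ilvB and leuC were among 43 that rose at 2.5%. Thinning to 10000 counts kept 0.976 ± 0.041 (SD of 10 thinnings) of the median change of the called genes. This argues against depth as the whole cause of the size of the change. In 1 thinning 23 of 361 genes were called, against 117 of 1108 in full. A second source of counts may contribute: the slope within diet groups was 0.27 ± 0.15 on the genome total, within 2 SE of 0, and 0.31 ± 0.14 on the counts outside the called genes (SE, n = 37), but within 2 SE there too without 0% replicate 3, 4 or 9, 0.5% replicate 4, 1% replicate 5 or 9, or 2.5% replicate 6, while the count of 17 genes with the genome total as a covariate removes dose along with it. A response of this bacterium to broccoli, a change of strain and cage stay open, untested.

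In F. rodentium, frlB, manZ_1 and deoC were among 91 genes that rose and ydjF and cbh_1 among 68 that fell at 2.5%, while its total dropped. Depth cannot be told apart from the diet, since thinning kept 0.659 ± 0.074 of the median change, between the bounds, and in 1 thinning edgeR called 0 of 392 genes (11 at an unadjusted p under 0.05; no other tool was run), a loss that fewer counts alone can bring. A second source of counts that weighs more as the bacterium declines may contribute: the slope within diet groups was -0.22 ± 0.07 (SE, n = 38), both on the genome total and on the counts outside the called genes, though 0.09 ± 0.11 within the 0% group alone. A response of this bacterium to broccoli and cage stay open, untested.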

How the results depend on the processing

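The genome total as a covariate, libraries with at least 50% of the features detected, the 5 most counted features left out, fits without 2.5% replicate 8 or 9, and fits without a library far from its group were chosen after the data were seen. No paired analysis was possible because replicate numbers follow the order of the samples and the labels pair no mice. A minimum of 50000 counts could not be run in Acetatifactor, D. muris and X. muris, which left no 0% library, nor could X. muris without its 5 top features. The fit on libraries with at least 50% of the features was run in D. muris and F. rodentium only. Where a count or call moved, the cause was not tested unless stated. Of the 165 genes named by the rule, 149 kept their direction and their side of the threshold with RLE factors, 156 with DESeq2, 163 without the low-count filter, 160 without a minimum, 148 without libraries 76 to 81, 82 with the covariate, and 165 and 156 without 2.5% replicate 9 and 8. With a minimum of 50000 counts 79 of 92 did, with 50% of the features detected 39 of 43, and without the 5 top features 150 of 151. Without the library far from its group for a gene, 3 of 87 calls were lost, those of glgP_1 at 0.5% (-0.62, edgeR adjusted p = 0.114) and of btuB_4 and ftsI at 2.5%, and 4 were gained: ilvC at 0.5% in Acetatifactor (4.02, without 0% replicate 8), licC at 1% in F. rodentium (1.21, without 0% replicate 10), rnr at 0.5% (2.37, without 0.5% replicate 5) and nifJ at 1% (1.02, without 1% replicate 2) in X. muris. Calls were also lost for cpdA_3 and graR_4 of Acetatifactor with DESeq2, for btuB_4 and ftsI with no minimum, for mutB without the filter or its genome's 5 top features, for cobB and trxB with RLE factors and for gdhA and mce with DESeq2. Depth limits Alistipes, F. rodentium at 2.5% and X. muris at 0% and 0.5%.

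With RLE factors 370 genes of Acetatifactor were called at 0.5%, 45 of X. muris at 2.5% and 1171 slopes of L.bacterium335, and hisC_3 (0.07) and recD2_1 (0.71) reversed in L.bacterium335. With DESeq2 Acetatifactor gave 1033, 1782 and 2553 calls at 0.5, 1 and 2.5% and 2538 slopes, F. rodentium 246, 27, 269 and 210, and L.bacterium335 2086, 2407, 2869 and 2918, with hisC_3 at 0.06 and recD2_1 at 0.71. The DESeq2 fits used no low-count filter, so their counts and splits cover more features than those of edgeR. Without the low-count filter Acetatifactor gave 811, 1852 and 2538 calls and 1917 slopes, and L.bacterium335 2374, 2770, 3252 and 2807. D. muris then gave 180 at 2.5% and 147 slopes, F. rodentium 19 at 1%, and X. muris 159 slopes. The split of higher and lower calls moved by over 10 points in places. It was 362 and 8 with RLE and 1020 and 13 with DESeq2 for Acetatifactor at 0.5%, 479 and 8, and 1761 and 21, at 1%, 2525 and 28 with DESeq2 at 2.5%, and 528 and 22, and 2507 and 31, for its slope. In F. rodentium it was 134 and 112 at 0.5% and 191 and 78 at 2.5% with DESeq2, and 64 and 22, and 142 and 68, for its slope. In L.bacterium335 slopes it was 1142 and 29, and 2875 and 43, and in X. muris at 1% 22 and 10, and 16 and 14.

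Without libraries 76 to 81, Acetatifactor gave 87 calls, D. muris 18 and F. rodentium 40 at 0.5%, F. rodentium 102 at 2.5% and L.bacterium335 1156 slopes. The 1% share of F. rodentium then passed the test (-30.4 points). Gene lists called became 1 at 2.5% in Acetatifactor, 1 in F. rodentium and 1 in L.bacterium335, and 2 for the slope in F. rodentium, whose tryptophan list lost its 2.5% call (camera adjusted p = 0.0546). Those 2 slope lists, tryptophan and purine and pyrimidine (camera adjusted p = 0.0368 and 0.0321), had adjusted p = 0.563 and 0.650 with an estimated correlation in all libraries. With an estimated correlation camera called 0 lists in the slope of Acetatifactor, at 2.5% and in the slope of D. muris, and at 2.5% in F. rodentium. With no minimum of counts D. muris gave 36 calls at 0.5%. With 50% of the features detected it gave 42 at 1%. With a minimum of 50000 counts F. rodentium gave 102 calls at 2.5% and 34 slopes, and L.bacterium335 254 slopes. A slope on the dose rank gave 1145 slopes in L.bacterium335, and leaving out 2.5% replicate 8 or 9 gave from 543 to 1033.

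With the genome total as a covariate, which itself differs between doses, Acetatifactor gave 100, 85 and 18 calls and 2 slopes, and yesX reversed (-0.11). D. muris gave 16, 24 and 17 calls and 0 slopes (edgeR, 56 at an unadjusted p under 0.05), F. rodentium 3 at 1% and 34 slopes, and L.bacterium335 0 slopes (edgeR, 170 at an unadjusted p under 0.05). X. muris gave 19 at 1%, 18 at 2.5% and 13 slopes.

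As centred log-ratios on the log2 scale, the shares of Acetatifactor reversed at 1% (-0.15) and 2.5% (-0.23), D. muris at 2.5% (-0.11) and X. muris at 0.5% (-0.26). D. muris at 1% (0.32), L.bacterium335 at 2.5% (0.89) and X. muris at 1% (0.25) and 2.5% (0.60) missed the test, and F. rodentium at 1% passed it (-2.10). This alternative weighs the genomes equally, so the fall of F. rodentium (-5.74 at 2.5%) counts as 1 of 6 parts. The rise of Alistipes (4.59 at 2.5%), from 51 to 336 counts per 0% library, counts as much and lowers the other values. Without the 5 most counted features of each genome, Acetatifactor (5.43), F. rodentium (-32.6) and L.bacterium335 (19.0 points) passed the test at 1%, and F. rodentium (-2.14) and L.bacterium335 (0.903 points) reversed at 0.5%. Without 2.5% replicate 9 the 2.5% share of Acetatifactor was 6.25 points higher. Features of Acetatifactor at an equal depth at 0.5% were 353.9 higher without libraries 76 to 81 (permutation test, adjusted p = 0.0623).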

Other observations

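The number of features at an equal depth was chosen as a measure after the data were seen, and so were its tests. At 10000 counts, an L.bacterium335 library at 0% was expected to show 371.8 ± 51.4 features (SD, n = 10), against 1131 ± 215.5 at 0.5%, 1233 ± 397.1 at 1% and 1564 ± 435.3 at 2.5%. Libraries above every 0% library numbered 10, 10 and 9 of 10 (two-sided permutation tests, adjusted p = 0.0001, 0.0001 and 0.0003 over 15 tests). Acetatifactor went from 631.3 ± 221.8 to 1054 ± 451.7, 1403 ± 201.8 and 1675 ± 517.8 (permutation tests, adjusted p = 0.0223, 0.0001 and 0.0003), and without libraries 76 to 81 the 0.5% difference, 353.9 features, missed the test (permutation test, adjusted p = 0.0623). X. muris went from 513.1 ± 289.8 (n = 7) to 974.3 ± 211.1 at 1% and 1233 ± 144.7 at 2.5% (exact permutation tests, adjusted p = 0.00583 and 0.000983), and 690.7 at 0.5% missed the test (exact permutation test, adjusted p = 0.406).

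D. muris, which already spread its counts widely at 0% (1256 ± 74.6 features, n = 9), rose less, to 1380, 1365 and 1444 ± 93.6 (exact permutation tests, adjusted p = 0.0125, 0.000433 and 0.000441). F. rodentium had 1123 ± 54.0 at 0% and 1159 ± 114.3 at 2.5% (exact permutation test, adjusted p = 0.423). The 5 most counted features took a median of 89.9% of X. muris counts at 0% and 53.2% at 2.5%, and 56.8% and 28.7% in Acetatifactor.

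Other assignments of the libraries to the doses were drawn 100 times per comparison, the real one included. For 19 of 20 gene counts only the real one (1 of 100) called as many genes, which is the smallest share these draws can give. Single mice were reassigned, so the draws take no account of shared cages. The real count and the highest other were 194 and 162, 524 and 57, 595 and 3, and 488 and 5 in Acetatifactor (0.5, 1 and 2.5% and slope). In D. muris they were 55 and 6, 69 and 3, 117 and 24, and 92 and 1, and in F. rodentium 143 and 66, 8 and 1, 159 and 17, and 101 and 10. In L.bacterium335 they were 1109 and 414, 1106 and 888, 1285 and 9, and 638 and 1. In X. muris they were 44 and 6 at 1%, 74 and 19 at 2.5% and 49 and 2 for the slope. At 0.5% X. muris had 0 edgeR calls (89 at an unadjusted p under 0.05, 0 by DESeq2, and 7 by edgeR without 0.5% replicate 5), 100 of 100 assignments gave as many, and the highest was 15.

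For the gene lists chance assignment cannot be excluded. As many lists were called in 33 of 100 assignments for the Acetatifactor slope (1 list, highest other 4), 26 for D. muris at 2.5% (1, highest 2), 35 for its slope (1, highest 3) and 38 for F. rodentium at 2.5% (2, highest 6).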
